A study of Mus musculus with 2 samples.

How the data were processed

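The 2 samples were chromatin immunoprecipitation libraries of mouse lung at embryonic day 15.5, made per the labels with an antibody against histone H3 trimethylated at lysine 4 (H3K4me3). They formed 1 group of 2 biological replicates, with tissue pooled from 78 embryos in replicate 1 and from 62 in replicate 2, and sex mixed in both pools. The 4 lists of peaks used were those of replicate 1, of replicate 2, of both replicates together, and of replicated peaks. Each list of a single replicate was derived from that replicate's alignments and 1 control file, per the text files deposited with the samples. The same texts state that the list of both replicates together was made from both sets of alignments and 2 control files, and that the replicated list was derived from it and from the 2 replicate lists. They also give the mm10 build and the narrowPeak layout. The aligner, the peak caller, its version, its threshold and the rule for calling a peak replicated were not given in the sources used here.

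The deposited columns were read by the narrowPeak layout. The score of each peak, scaled by the authors to at most 1000, was not used. The fold enrichment of each peak over control was the authors' own value. That it is such a ratio was read from the layout, from its range and from the named control files, since the deposited texts do not describe it. The p-value and the q-value of each peak were deposited by the authors on the −log10 scale. The lowest −log10 p was 2.00 in replicate 1, 2.03 in replicate 2, 2.00 in the list of both replicates together and 2.26 in the replicated list. A q-value above 0.05 was held by 3.40%, 2.59%, 1.90% and 0.0471% of the peaks in those lists. Fold, p and q served only to rank and describe peaks within their own list, and no ratio between lists was formed from them. Read counts were not given in the sources used here, so sequencing depth is unknown and no interval or limit that needs it was computed. Signal tracks were not used here.

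Positions were read against the GRCm38 sequence, the same build as mm10, with GENCODE release M 21 (Ensembl 96). A promoter window reached 1 kb each side of every annotated transcript start of a protein-coding gene. A gene counted as marked when a peak overlapped such a window by at least 1 bp. The gene's own 5′ end was the outermost start of the annotated gene, and whether it is the gene's main start was not examined. Peaks no more than 1 kb apart were joined, and the widest joined run touching a gene's windows was its domain. A peak over 5 kb from every annotated start of any gene was called distal. Promoters were CpG-rich when the CpG observed/expected ratio was at least 0.6 and the GC fraction at least 0.5 over 1 kb each side of the gene's 5′ end, and CpG-poor otherwise. Peaks on unplaced scaffolds were left out of every comparison by position. All coordinates count from 1.

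The 18 gene lists, the tests, the rule for named genes and most of the other settings tried were fixed before the data were examined. The lists covered regulators and products of lung epithelium, lung mesenchyme, endothelium, mesothelium, blood and immune cells, autonomic neurons and glia, and cartilage. Lists for forebrain, heart muscle, skeletal muscle, liver, gut and pancreas, and germline and pluripotency stood for tissues the dissection could hold or should lack. Hox, cell cycle, ribosomal protein and olfactory receptor genes completed them. All symbols matched the annotation, and 1 of them, Tf in the liver list, matched under the name Trf. Leaving out olfactory receptors, the lists held 370 genes. Named were the genes of the 20 widest domains, the 10 genes of highest fold enrichment, up to 3 marked and 3 unmarked members of each list, 11 genes named in every case, the 5 distal peaks of highest fold enrichment, and up to 5 genes with a promoter peak in a single replicate.

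The marked share of each list was compared with that of all other protein-coding genes by a two-sided Fisher's exact test. The same test compared the share of marked genes in the widest 5% of domains, and the marked shares of CpG-rich and CpG-poor promoters. Median widths of the 15 lists with at least 5 marked members were set against 100000 random sets of marked genes in a two-sided permutation test, whose smallest p is 2e-05. Each family of list tests was adjusted by the Benjamini-Hochberg method, with an adjusted p of 0.05 as the threshold. Exact probabilities under 1e-300 are given as below 1e-300. Shares carry exact Clopper-Pearson 95% intervals. Overlaps were compared with 100 random placements of the peaks within their chromosomes. The interval of the rank correlation came from 1000 resamples of whole chromosomes. Genes and peaks are not independent replicates, and with 2 samples of 1 group no p-value was computed across samples.

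Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1. The list tests were tested on simulated data built on the 21938 protein-coding genes, with 20 genes to a list. Lists made with 98% of their genes marked were called in 87.5% of 40 cases and lists made with 30% marked in 82.5% of 40, against 1.25% of 80 unchanged lists. Widths multiplied by 2 were called in 95% of 40 lists, against 2.5% of 80 unchanged lists. The alternatives tried were windows of 500 bp and 2.5 kb, the gene's own 5′ end alone, no joining and joining over 3 kb, the widest 10%, a CpG ratio of 0.75, distal limits of 1 kb and 10 kb, an overlap of at least 50%, the 50% of peaks with the best q-values, the list of both replicates together, peaks found in both replicate lists, protein-coding starts only for distal peaks, ranks by width, no peak of the other replicate within 2.5 kb, and each replicate left out in turn. Settings chosen after the results were seen were 1 gene per domain, CpG-rich promoters only, CpG-poor promoters only, a background without olfactory receptors, and promoter peaks that no peak of the other replicate overlaps. With 1 gene per domain a list member was kept wherever a domain held one. This favours the lists among wide domains that several genes share.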

Results

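H3K4me3, a histone mark that surrounds the starts of active genes and of genes held ready for activation, was mapped by chromatin immunoprecipitation and sequencing in mouse lung at embryonic day 15.5. At that age the airway tree is still branching. There was 1 group of 2 biological replicates, with no untreated or other group beside it. Replicate 1 was lung tissue pooled from 78 embryos, and its list held 29511 peaks over 38.3 Mb with a median width of 954 bp and a median fold enrichment of 11.1. Replicate 2 was pooled from 62 embryos, and its list held 26789 peaks over 34.6 Mb with a median width of 1041 bp and a median fold enrichment of 13.0. The list of both replicates together held 29431 peaks over 40.3 Mb. The replicated list held 23368 peaks over 38.7 Mb, or 1.42% of the chromosomes, with a median width of 1467.5 bp and a median fold enrichment of 23.1. Sequencing depth is unknown, because the lists hold no read counts.

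The first comparison was between the replicates. Some domains at genes of lung development had nearly equal widths in both, and others did not. At Nkx2-1, the homeobox gene that marks lung epithelium from its origin, the domain was 20.7 kb in each replicate. Hoxb3 to Hoxb6, neighbouring genes of the HoxB cluster that pattern the body axis, shared a domain of 30.7 kb in replicate 1 and 31.0 kb in replicate 2. Nr2f2, an orphan nuclear receptor of mesenchyme and venous endothelium, had 25.1 kb and 24.9 kb, and Tbx5, a T-box gene of lung mesenchyme, had 17.3 kb and 16.4 kb. Foxf1, a forkhead gene of lung mesenchyme, differed more, with 18.1 kb in replicate 1, where peaks upstream were joined, and 12.8 kb in replicate 2, as did Fgf10, the growth factor that drives branching, with 5.39 kb and 4.31 kb. Epithelial regulators had median widths of 7.39 kb and 6.48 kb.

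Of the replicate 1 peaks, 79.1% overlapped a replicate 2 peak, and of the replicate 2 peaks, 92.3% overlapped a replicate 1 peak, a mean of 85.7%. Both shares describe the same overlap between lists of unlike length, so their difference is no spread between replicates. With the same number of top peaks by fold enrichment from each list they were 84.5% and 90.4%. Random placements gave at most 2.82% and 3.08%. The covered bases had a Jaccard index of 0.817. Across 22482 matched peaks the ranks by fold enrichment correlated with a Spearman rho of 0.935, with a 95% interval of 0.930 to 0.941, and ranks by width with a rho of 0.962. These are correlations across peaks, which are not independent replicates. The peaks without a partner, 6160 in replicate 1 and 2066 in replicate 2, had median widths of 248 bp and 225 bp and median fold enrichments of 3.12 and 2.82. All of them lay in the weaker 50% of their list.

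The replicated list held the strong and wide part of what both replicates gave together. It kept 79.4% of the 29431 peaks. Of the weakest 10% of peaks by fold enrichment 6.62% were kept, of the next 10% of peaks 24.5%, then 65.6% and 97.3%, and all of the stronger ones. The 6063 peaks left out had a median width of 244 bp and a median fold enrichment of 2.55. Among the replicated peaks, 22192 of 23368 (95%) overlapped peaks of both replicate lists, against 42 of the 6063 left out (0.693%).

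The next comparison asked where in the genome the mark lay. Most replicated peaks sat at promoters of protein-coding genes. The highest fold enrichment was 77.9 at Arl8b, a small GTPase of lysosome transport, followed by 77.1 at Eif4e, the cap-binding initiation factor, 76.9 at Npepps, an aminopeptidase, and 76.7 at Hnrnpf, an RNA-binding protein. Zbtb17, Nf2, Pias1, Nsd2, Fbxo21 and Cnnm3 followed with 75.5 to 75.9. The domain at Arl8b was 2.62 kb wide and that at Eif4e 3.10 kb.

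Of 23358 replicated peaks on chromosomes, 15416 (66.0%) overlapped a protein-coding promoter, against a median of 6.55% and a maximum of 7.06% in random placements. The share was 57.6% in replicate 1 and 62.3% in replicate 2, a mean of 60.0% ± 3.31 (SD, n = 2). Starts of other annotated genes held 5.51% of the peaks, exons 3.10%, introns 9.97% and intergenic sequence 15.4%. Introns and intergenic sequence took 31.8% and 55.4% of randomly placed peaks. Around the 5′ ends of protein-coding genes, coverage was highest 200 bp downstream, where 60.7% of genes lay under a peak. It was 17.8% at 1 kb upstream and 48.8% at 1 kb downstream.

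**Figure D1:**
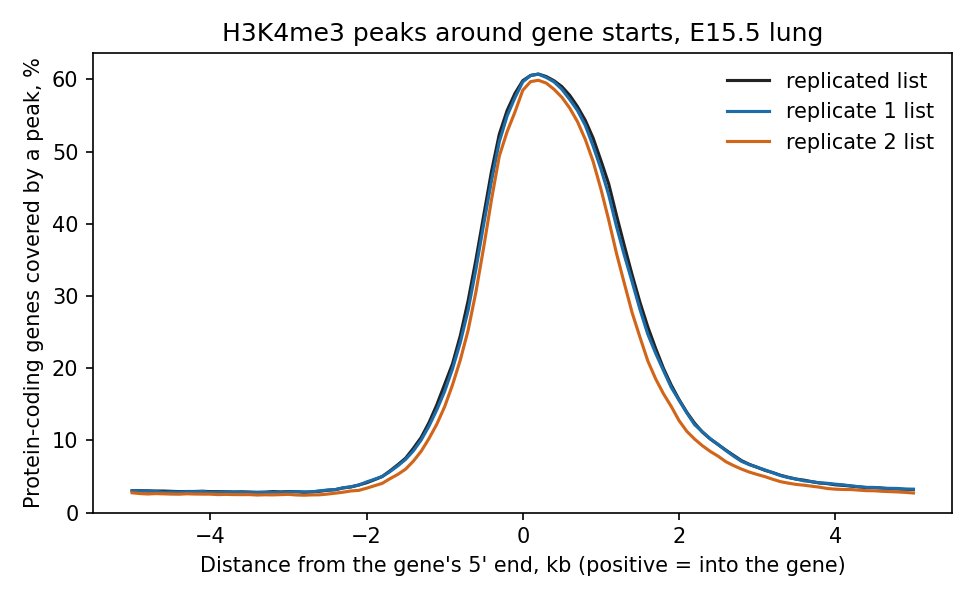
Percent of protein-coding genes covered by a peak (y axis) against the distance from the gene's 5′ end in kb (x axis), with 1 line each for the replicated list, replicate 1 and replicate 2. The replicated line was highest at 60.7% just downstream of the 5′ end and was 3.03% at 5 kb upstream and 3.19% at 5 kb downstream.

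The next comparison asked which genes were marked. All 33 mesenchyme genes carried the mark, among them Tbx4, Tbx5, Foxf1 and Fgf10. So did 27 of 28 epithelial regulators, including Nkx2-1, Sox2 of the proximal airway and Sox9 of the distal tips. In the endothelial list 29 of 30 genes were marked, with Pecam1 among them. Products that appear as airway and alveolar cells mature were marked in 11 of 28 cases. Sftpc, the surfactant protein of alveolar type II cells, was marked, while the secretory products Scgb1a1, Bpifa1 and Cyp2f2 were not, although replicate 1 held a peak of 0.274 kb at Cyp2f2.

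Over the whole genome 14653 of 21938 protein-coding genes (66.8%) were marked, with 67.4% in replicate 1 and 66.7% in replicate 2, a mean of 67.1% ± 0.509 (SD, n = 2). The marked share was higher than among other genes, by Fisher's exact test adjusted over 18 lists, in 6 lists. These were lung mesenchyme (100%; adjusted p 1.38e-05), epithelial regulators (96.4%; 7.36e-04), endothelium (96.7%; 2.89e-04), Hox genes (34 of 39, 87.2%; 0.00957), cell cycle genes (25 of 25; 1.67e-04) and ribosomal protein genes (34 of 34; 1.24e-05). The unmarked member was Ehf, an epithelial Ets factor, in the epithelial list and Vwf, the clotting factor of mature vessels, in the endothelial list, although replicate 2 held a peak of 0.263 kb at Vwf. Unmarked Hox genes were Hoxc8, with a peak of 0.477 kb in replicate 1 alone, Hoxc11 and Hoxc12, and 2 chosen after their values were seen, Hoxd10 and Hoxd12.

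The share was lower in 5 lists. Of the liver list 2 of 16 genes were marked (12.5%; adjusted p 5.07e-05): Apoh, whose domain also held the start of Prkca, and the transferrin gene Trf, whose domain also held that of Gm20425. Albumin (Alb), Afp and Ahsg were unmarked. Of the germline and pluripotency list 3 of 16 were marked (18.8%; 2.84e-04), namely Sox30, Dazl and Dppa3, with domains of 0.456 kb to 1.38 kb. Of the blood and immune list 9 of 30 were marked (30%; 1.67e-04), led by Runx1, Gata2 and Tal1, regulators of blood formation that also act in endothelium. The pan-leukocyte gene Ptprc was unmarked, as were Adgre1, Alas2 and Cd19. Of the alveolar and airway products 39.3% were marked (95% interval 21.5% to 59.4%; 0.00703). Of 1135 olfactory receptor genes 3 were marked (0.264%; p below 1e-300), namely Olfr94, Olfr56 and Olfr1033. Globin genes in the blood list and many olfactory receptors have near-identical copies, and how reads shared between copies were treated was not given in the sources used here.

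In 7 lists the marked share did not differ from other genes at this threshold. These were mesothelium (8 of 12; adjusted p 1), autonomic neurons and glia (10 of 15; 1), cartilage (11 of 12; 0.166), forebrain (14 of 16; 0.164), heart muscle (6 of 12; 0.276), skeletal muscle (7 of 12; 0.617), and gut and pancreas (6 of 12; 0.276). Among them Msln, Phox2b, Matn1, Neurod6, Myh6, Acta1 and Ins1 were unmarked, while Wt1, Hand2, Sox6, Dlx2, Ryr2, Pax7 and Lgr5 were marked. With the 50% of peaks of best q-value the endothelial call ended at 50% marked (adjusted p 0.715, range 2.99e-05 to 0.715 over 10 alternatives). The Hox share turned to lower at 25.6% (adjusted p 5.77e-04) and the forebrain share from 87.5% to 0% (1.20e-05), both past the threshold. The same peaks gave lower shares past the threshold in mesothelium (0%; adjusted p 2.08e-04), autonomic genes (26.7%; 0.0454), heart muscle (8.33%; 0.00264) and gut and pancreas (8.33%; 0.00264), each the lowest over 10 alternatives, whose highest were 1, 1, 1 and 0.486. Heart muscle was also lower with own 5′ ends (25%; 0.0202), and cartilage was higher among CpG-poor promoters (90%; 0.0425, range to 0.320). Among genes with CpG-poor promoters alone, an alternative chosen after the data were seen, the calls of epithelial regulators and alveolar products ended. Their marked shares were 88.9% and 32.0% (both adjusted Fisher's exact p 0.0660, the highest over their 10 alternatives), against 53.0% of all genes with CpG-poor promoters. The Hox call ended with own 5′ ends (0.143, the highest of 10) and with peaks found in both replicate lists (0.0679).

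**Figure D2:**
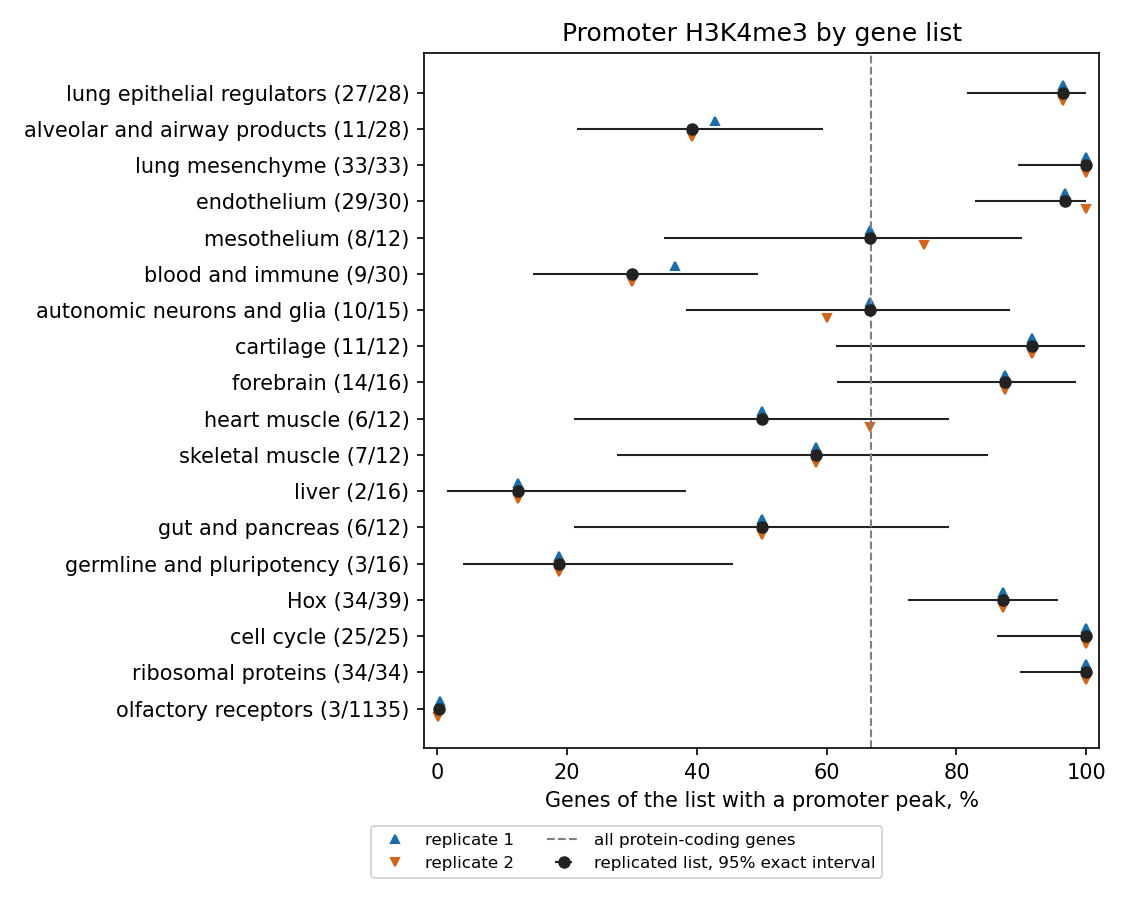
Percent of each list's genes with a promoter peak (x axis) for the 18 gene lists, with points for the replicated list, bars for exact 95% intervals, triangles for the 2 replicates and a dashed line at the 66.8% of all protein-coding genes. Mesenchyme, cell cycle and ribosomal protein genes sit at 100%, and olfactory receptors at 0.264%.

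Domain width also differed between the lists. Epithelial regulators had a median width of 6.44 kb, mesenchyme genes 4.87 kb and endothelial genes 3.84 kb, against 2.27 kb for all marked genes. Among epithelial regulators Nkx2-1 stood at 20.7 kb (chromosome 12, 56518247 to 56538981), Irx5 at 15.1 kb, Irx2 at 13.5 kb, the pioneer factor Foxa2 at 13.2 kb and Foxa1 at 12.6 kb. Shh, the signal from epithelium to mesenchyme, stood at 10.7 kb, Sox9 at 6.02 kb and Sox2 at 5.85 kb. In mesenchyme Tbx5 had 17.1 kb, Tbx2 16.3 kb, Ptch1, the hedgehog receptor, 16.3 kb, Tbx3 15.6 kb, Foxf1 12.9 kb (chromosome 8, 121078611 to 121091461) and Tbx4 11.1 kb.

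Endothelial genes with wide domains were Egfl7 (9.97 kb), Notch4 (8.35 kb, shared with the starts of Gpsm3 and Pbx2) and Dll4 (7.5 kb), the last a Notch ligand of arterial and sprouting cells. At its own 5′ end Notch4 had 1.53 kb. Fgf10 had a domain of 5.44 kb and Pecam1 one of 3.57 kb, both at annotated starts 43.5 kb and 27.7 kb from the gene's own 5′ end. The domain of Sftpc was 6.75 kb (chromosome 14, 70517574 to 70524319) and also held a start of Bmp1. Cldn18 and Pdpn, of alveolar epithelium, had 3.72 kb and 4.22 kb, though Cldn18 had no peak within 1 kb of its own 5′ end.

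Against random sets of marked genes, 7 of 15 lists differed in median width. Wider were epithelial regulators, mesenchyme and endothelium (adjusted permutation p 1e-04 each, from the smallest p the random sets can give) and cell cycle genes (3.21 kb; 0.00258), where Ccnd2 had 8.14 kb, Ccnd1 6.49 kb and Plk1 4.38 kb. Narrower were gut and pancreas (0.731 kb; 4.50e-04), heart muscle (1.23 kb; 0.0236) and skeletal muscle (1.24 kb; 0.0236). The gut and pancreas regulators Cdx1 and Ptf1a had 0.731 kb and 1.36 kb, while Lgr5, a receptor of stem cells, had 3.37 kb. In heart muscle Ryr2 had 2.23 kb, Gata4 2.10 kb and Tbx20 1.44 kb, though Gata4 had no peak within 1 kb of its own 5′ end. In skeletal muscle Pax7 had 2.11 kb, whereas the 4.66 kb of Mylpf and the 2.09 kb of Actn3 also covered the starts of Tbc1d10b and Zdhhc24.

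Replicate medians were 6.93 kb ± 0.648 for epithelial regulators, 4.51 kb ± 0.171 for mesenchyme, 3.93 kb ± 0.571 for endothelium and 3.19 kb ± 0.320 for cell cycle genes (SD, n = 2 each). Among the narrow lists they were 0.770 kb ± 0.375 for gut and pancreas, 1.21 kb ± 0.567 for heart muscle and 1.16 kb ± 0.127 for skeletal muscle, against 2.18 kb ± 0.129 for all marked genes (SD, n = 2 each). The heart muscle call ended without replicate 2 (1.61 kb; adjusted permutation p 0.171) and with joining over 3 kb (2.48 kb; 0.965, the highest over 10 alternatives), which also ended the skeletal muscle call (2.09 kb; 0.773, the highest over 11). The cell cycle call ended among CpG-rich promoters, chosen after the data were seen (3.41 kb; 0.0915, the highest over 13 alternatives), the skeletal muscle call also with windows of 500 bp (1.66 kb; 0.215), and both muscle calls among CpG-poor promoters (0.0624 each), although the medians there, 1.02 kb and 1.03 kb, were narrower than with all promoters.

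The other 8 lists were not called. Ribosomal protein genes had a median of 2.77 kb (adjusted permutation p 0.0507), with Rps11 at 7.31 kb, Rpl35 at 6.89 kb and Rps2 at 6.03 kb. They passed as wider in 9 of 13 alternatives (0.00800 to 0.726 over the 13), among them replicate 2 alone (0.0198) and replicate 1 alone (0.0319). Hox genes had 1.90 kb (0.0851), cartilage genes 2.79 kb (0.251), mesothelium 2.26 kb (0.964), blood and immune genes 2.15 kb (0.8), forebrain genes 2.13 kb (0.732), autonomic genes 1.89 kb (0.325) and alveolar and airway products 1.79 kb (0.22). Individual members were wide, such as Runx1 at 7.60 kb, Sox6 at 5.12 kb, Gata2 at 4.89 kb, Tal1 at 4.63 kb, Col2a1 at 4.45 kb and Hand2 at 4.32 kb. At the gene's own 5′ end, however, Runx1 had 0.683 kb, Gata2 0.994 kb and Sox6 2.84 kb. That end is the outermost annotated start, so the wide domains may still lie at the gene's main start. Hox medians depended on the peaks used, with 9.87 kb among the 50% of best q-value, where 10 of 39 genes stayed marked. They passed as narrower with own 5′ ends (1.65 kb; 0.00467), windows of 2.5 kb (1.83 kb; 0.0372), 1 gene per domain (1.69 kb; 0.0244) and CpG-rich promoters (1.65 kb; 5.33e-05), within a range of 4.00e-05 to 0.249 over 13 alternatives. In 1 alternative each, alveolar and airway products passed as narrower with the pooled list (0.0127, range to 0.965), blood and immune genes as wider with joining over 3 kb (0.0363, range to 0.922) and forebrain genes as narrower without joining (0.0497, range to 0.965).

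**Figure D3:**
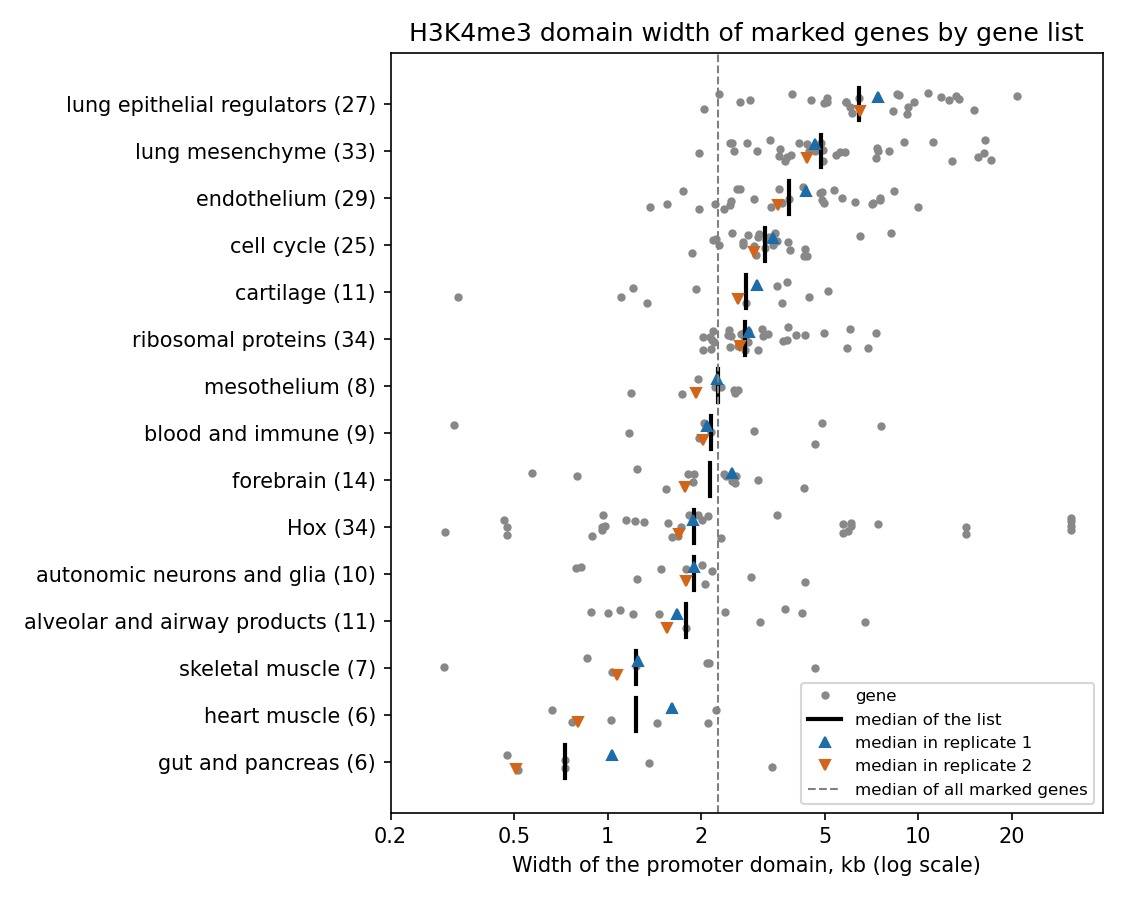
Width of each marked gene's H3K4me3 domain in kb on a log scale (x axis) for 15 gene lists (y axis), with grey points for genes, black bars for list medians, triangles for replicate medians and a dashed line at the 2.27 kb median of all marked genes. Epithelial regulators had the highest median, 6.44 kb, and gut and pancreas genes the lowest, 0.731 kb.

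The next comparison took the widest domains of the genome. The 31.0 kb of Hoxb3 to Hoxb6 (chromosome 11, 96298795 to 96329803), the 25.1 kb of Nr2f2 (chromosome 7, 70345763 to 70370878) and the 20.7 kb of Nkx2-1 led the list. Nfib, a factor of lung maturation, had 17.5 kb, and the T-box genes Tbx5, Tbx2 and Tbx3 and the receptor Ptch1 stood among the next. Nfib and Hoxb6 had no peak within 1 kb of the gene's own 5′ end, so their domains lay at other annotated starts. Meis1, a partner of Hox proteins, had 14.6 kb, Zeb2, a zinc-finger repressor, 14.3 kb, the pair Hoxa1 and Hoxa2 14.3 kb, and Smad7, an inhibitor of transforming growth factor signalling, 12.9 kb. Others were Setd1b, with 13.9 kb, a methyltransferase of this mark, the demethylase Kdm6b with 12.9 kb and Bahcc1 with 12.7 kb.

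The widest 5% were domains of at least 4.91 kb and belonged to 737 genes in 584 domains. By Fisher's exact test adjusted over 18 lists, 4 lists were over-represented there. They were epithelial regulators (21 of 27, 77.8%; adjusted p 1.64e-21), mesenchyme (16 of 33, 48.5%; 6.73e-12), Hox genes (12 of 34, 35.3%; 2.84e-07) and endothelium (10 of 29, 34.5%; 3.67e-06). With joining over 3 kb the epithelial share was 48.1% (2.12e-09, range 1.41e-21 to 6.79e-05 over 11 alternatives), and the Hox share was 20.6% without joining (0.00564), 22.2% with 1 gene per domain (0.00826) and 70% among the 50% of peaks of best q-value, with a highest adjusted p of 0.0298 over 11 alternatives. Ribosomal protein genes reached 5 of 34 (0.0948) and cell cycle genes 2 of 25 (0.867). Alveolar and airway products had Sftpc (1 of 11), blood and immune genes Runx1 (1 of 9) and cartilage Sox6 (1 of 11), each with adjusted p 0.867. In mesothelium, autonomic, forebrain, heart muscle, skeletal muscle, liver, gut and pancreas, germline and olfactory lists no gene reached that width (adjusted p 1 each). Single widths rested partly on joining and on replicate 1. Without joining Nr2f2 had 8.73 kb, Nkx2-1 13.0 kb, Foxa2 5.44 kb and the Hoxb genes at most 12.8 kb, while Nfib, Ptch1, Tbx3, Irx5, Bahcc1, Zeb2, Kdm6b, Setd1b, Hoxa1 and Hoxa2 had 4.24 kb to 11.2 kb. In replicate 2 alone Kdm6b had 7.15 kb and Rhof, which shares the Setd1b domain, 1.39 kb.

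**Figure D4:**
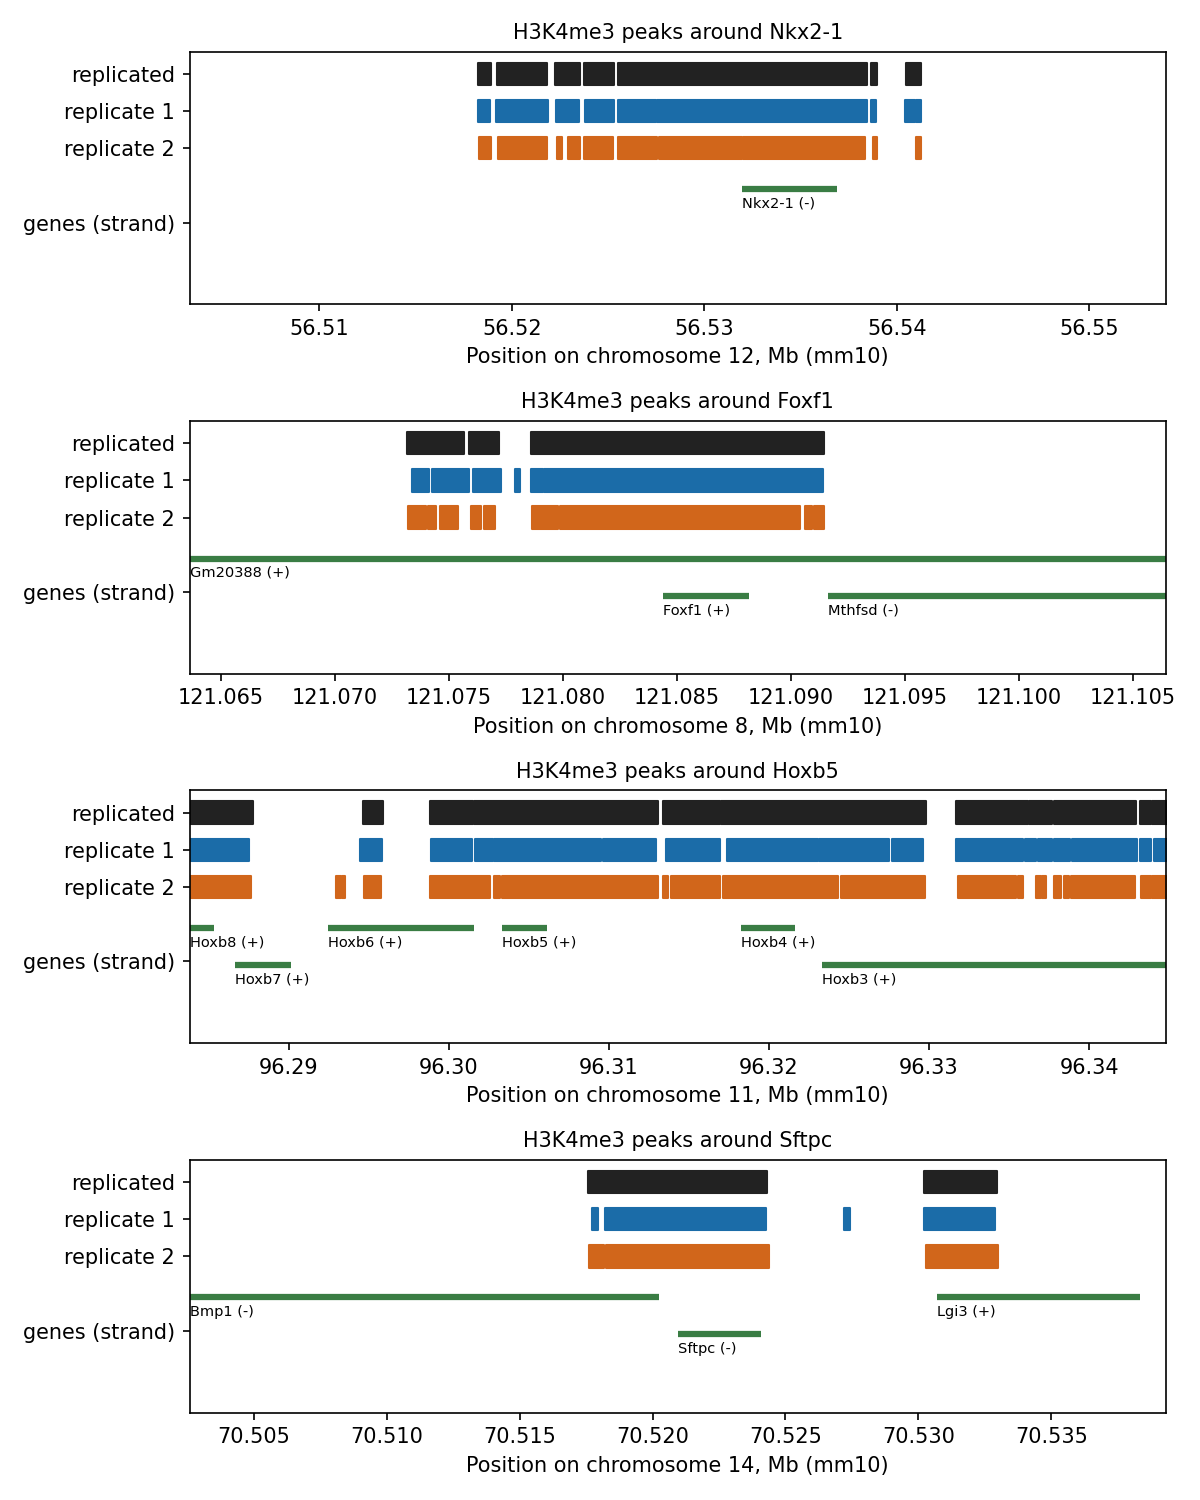
Maps of 4 regions on mm10 (x axis, position on the chromosome) around Nkx2-1, Foxf1, Hoxb5 and Sftpc. Bars show peaks of the replicated list and of each replicate, and lines show protein-coding genes, labelled with symbol and strand. The Nkx2-1 domain was 20.7 kb in each replicate, and the Foxf1 domain 18.1 kb in replicate 1 and 12.8 kb in replicate 2.

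The sequence of the promoter went with the mark. Genes with CpG-rich promoters, which include most housekeeping genes and many developmental regulators, were almost all marked. Tissue-restricted products such as Alb, Scgb1a1 and the olfactory receptors have CpG-poor promoters. Alb, Scgb1a1 and all but 3 of the 1135 olfactory receptors were unmarked. Of genes with CpG-rich promoters 6495 of 6532 were marked (99.4%, exact 95% interval 99.2% to 99.6%), with replicates at 99.4% ± 0.0433 (SD, n = 2). Of genes with CpG-poor promoters 8158 of 15406 were marked (53.0%, 52.2% to 53.7%), with replicates at 53.3% ± 0.707 (SD, n = 2). That class was not uniform. The marked share was 10.9% at a CpG ratio below 0.2, 46.8% from 0.2 to below 0.4 and 94.2% from 0.4 to below 0.6. Fisher's exact test gave a p below 1e-300. Domains of marked genes had a median of 2.72 kb in the CpG-rich and 1.90 kb in the CpG-poor class. The class describes the gene's 5′ end alone, whereas a peak at any annotated start counted as marking the gene. Gata4, for example, counted as marked but has a CpG-poor 5′ end with no peak within 1 kb. With own 5′ ends alone 63.1% of all protein-coding genes were marked, against 66.8%, and the classes were not compared under that setting.

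Some peaks lay far from annotated starts. The strongest was on chromosome 1 at 171037660 to 171039065, 18.7 kb from Fcgr4, an antibody receptor, and 9.70 kb from the nearest start of any gene, with a fold enrichment of 66.8. The next, on chromosome 12 at 8640196 to 8641763, lay 32.4 kb from Pum2, an RNA-binding regulator, with 64.8. A peak on chromosome 11 at 74637234 to 74639538 with 56.4 overlapped an exon of Ccdc92b. Another on chromosome 14 at 70190803 to 70193097 with 54.3 overlapped an exon of Sorbs3, 11.5 kb from its start. The last, on chromosome 9 at 32031641 to 32034119, lay 82.0 kb from Arhgap32 and 10.7 kb from the nearest start of any gene, with 53.3.

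In total 3903 replicated peaks (16.7%) lay over 5 kb from every annotated start, against a median of 73.7% and a minimum of 73.1% in random placements. Replicates gave 17.4% ± 1.61 (SD, n = 2). Distal peaks had a median width of 616 bp and a median fold enrichment of 5.39, against 1971 bp and 40.6 at protein-coding promoters, and 249 of them were in the stronger 50% of the list. The share was 28.5% with a limit of 1 kb and 2.18% among the 50% of peaks of best q-value.

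The final comparison asked which promoters carried a peak in a single replicate. Replicate 1 alone marked 214 genes and replicate 2 alone 56. The strongest in replicate 1 were Tnnc1, a troponin of slow and cardiac muscle, AC141477.1, 1700086D15Rik, and the epidermal genes Lor and Tchh. All 5 were also marked in the replicated list, where the nearest peak edge lay 0.882 kb to 0.990 kb from the gene's 5′ end, close to the limit of the window. In replicate 2 they were Cldnd2, Rgn, Dennd1c, Cytl1 with a peak of 0.415 kb, and Wnt8a with one of 0.439 kb. Of these, Cldnd2, Rgn, Dennd1c and Cytl1 were also marked in the replicated list. With windows of 500 bp Cldnd2, Rgn and Dennd1c were no longer marked there.

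These were weak peaks for the most part. Their median fold enrichment was 3.28 in replicate 1 and 3.19 in replicate 2, and 66.4% and 80.4% lay in the weakest 25% of their list. No list was over-represented among the replicate 1 genes by Fisher's exact test (0 lists called, lowest adjusted p 0.137, 2 lists at an unadjusted p under 0.05). Among the replicate 2 genes 1 list was called, heart muscle (adjusted p 0.00748), through Myh7 and Myl2, myosin chains of the ventricle with peaks of 0.190 kb and 0.191 kb. Among the 50% of peaks of best q-value the counts were 602 and 5, with 4 lists called in replicate 1 and 0 in replicate 2 (0 at an unadjusted p under 0.05). Each list was cut at its own median q-value, so replicate 1, with the longer list, kept more peaks. Of the replicate 2 peaks kept, 99.9% overlapped a kept peak of replicate 1. These counts cannot be read as a difference between the replicates, because the cuts were unequal.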

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

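Among the tests in this part, all but the comparison with RefSeq starts were chosen after the results they measure were seen. Sequence outside the comparisons held 10 replicated peaks, on 6 unplaced or unlocalized scaffolds, with a median width of 775.5 bp and fold enrichments from 2.65 to 51.4; they are given because their number is above the 3 that a count of 0 allows, although no count of 0 was predicted there. No biological explanation that needs a comparison between groups was tested for the patterns that follow, because the samples form 1 group.

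The first pattern is the width of domains at 47 marked regulators of lung cell types, such as Nkx2-1, Foxa2, Tbx5 and Foxf1, with a median of 5.85 kb. CpG content did not account for it, since the regulators stood at the median percentile of 97 among the 100 marked genes nearest in CpG ratio (2.52 kb in matched sets, 2.21 kb to 2.85 kb; permutation p 1e-05, the smallest possible). Joining of neighbouring peaks is not needed either, since the widest single peak had a median of 4.62 kb against 2.18 kb in random sets (1.87 kb to 2.52 kb; permutation p 2e-05, the smallest possible). Regulators of other organs and of autonomic neurons and glia, cells that lie in the lung too, were narrower by 4.18 kb, with a median of 1.66 kb over 26 genes (permutation p 1.50e-04), and by 4.49 kb without the 5 autonomic ones (1.36 kb over 21 genes; 5.80e-04). As a hypothesis found and tested on the same data, wide domains may mark regulators in use in the lung, though not these alone. Among the 26, Dlx2 had 4.27 kb. Outside both sets, Runx1 (7.60 kb), Sox6 (5.12 kb) and 12 of 34 Hox genes were in the widest 5%. Autonomic regulators were mostly not wide, with Hand2 at 4.32 kb, Ascl1 at 2.90 kb, Phox2a at 2.17 kb, Isl1 at 2.06 kb, Sox10 at 0.820 kb and Phox2b unmarked. Mesothelial regulators were not compared, and the mesothelium list, with regulators such as Wt1 (2.62 kb) and Tbx18 (2.54 kb), had a median of 2.26 kb. The share of cells that carry wide domains and the treatment of reads by the authors stay open.

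The next pattern is weak promoter peaks at regulators of other organs, such as Cdx1, Ptf1a and Pax7, in a set that also held 6 autonomic regulators, among them Ascl1 and Isl1 with its highest fold enrichments (32.6 and 32.1), and of which 26 of 30 were marked (21 of 24 without them). Their marked share of 86.7% was that of random sets matched on CpG ratio (76.7% to 96.7%), so CpG content may account for which of them carry a peak. It does not account for the low enrichment, which stood at the percentile of 32.2 against 73.0 in matched marked sets (63.3 to 81.8; permutation p 1e-05, the smallest possible) and 64.2 for lung regulators, and at 30.5 without the autonomic genes (61.8 to 82.6 in matched sets; 1e-05). Chance peaks of a single list are argued against by the replicate lists alone, since of 26 such genes with a promoter peak in replicate 1, 25 (96.2%, exact 95% interval 80.4% to 99.9%) had one in replicate 2, as did all 25 in the other direction. Cells of other organs in the tissue cannot be told apart from the lung's own weak marking, since 5 of 27 product genes of liver, heart and skeletal muscle with CpG-poor promoters were marked (18.5%, exact 95% interval 6.30% to 38.1%), among them Ckm, Actn3 and Trf in domains that also held the starts of Klc3, Zdhhc24 and Gm20425, and forebrain, gut and autonomic tissue were not covered.

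The last pattern is the 249 strongly enriched peaks over 5 kb from every annotated start, compared with 3654 weaker distal peaks. Starts missing from the annotation used may account for part of them, since 27.7% (69) lay within 1 kb of a RefSeq transcript start, against 9.55% (349) of the weaker ones (Fisher's exact p 6.26e-15). The strong peaks were wider, with a median of 1.44 kb against 0.59 kb. Wider peaks meet such a window more often by width alone, and no random placement was made for this test. CpG-rich sequence may add to it, as the median CpG ratio around their summits was higher by 0.199 (0.537 against 0.338; permutation p 1e-05, the smallest possible). Repeats or assembly faults were not tested and stay open, as do starts that neither annotation holds.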

How the results depend on the processing

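Alternatives with 1 gene per domain, CpG-rich promoters only, CpG-poor promoters only, a background without olfactory receptors, and promoter peaks that no peak of the other replicate overlaps were chosen after the results were seen. No paired analysis was possible because the 2 samples form 1 group with no other condition to pair them with. The 11 called marked shares kept direction and side of the threshold in 103 of 109 alternatives, 7 of the lists in every one run. The 7 called widths did so in 76 of 83, 4 of the lists (epithelial regulators, mesenchyme, endothelium, gut and pancreas) in every one run. The 4 lists called among the widest 5% did so in all 44, though 1 gene per domain, which is among these, keeps list members over their neighbours. Genes with CpG-rich promoters stayed above those with CpG-poor ones in all 8, by 37.6 to 54.3 points, none of which used own 5′ ends alone. Widths of named genes moved by more than the replicates' spread in 282 of 930 cases. Depth is unknown, so it was not tested what depth limits. Lists with under 5 marked members gave no width.

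The 50% of peaks with the best q-values hold fewer peaks by construction. The promoter share was then 93.9%, genes marked 54.4%, distal peaks 2.18%, pooled peaks kept 100%, replicate 1 peaks shared 89.8% and rank concordance 0.751. Genes marked in replicate 1 only were 602 (4 lists called, lowest adjusted p 2.82e-13) and in replicate 2 only 5 (0 lists called by Fisher's exact test, 0 at an unadjusted p under 0.05). These counts rest on unequal numbers of peaks, since each list was cut at its own median q-value. Marked shares turned for endothelium (50%) and cartilage (33.3%) without passing the threshold. For Hox (25.6%) and forebrain (0%) they turned and passed it as lower. Autonomic genes (26.7%), gut and pancreas (8.33%), heart muscle (8.33%) and mesothelium (0%) also became lower past it. The Hox width turned to 9.87 kb, and ribosomal proteins passed at 2.77 kb.

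Without a replicate, the promoter share ranged from 57.6% to 62.3%, genes marked from 66.7% to 67.4%, distal peaks from 16.3% to 18.6%, and the mesothelium share from 66.7% to 75%, which turned its direction without replicate 1. The forebrain width ranged from 1.77 kb to 2.51 kb, turned without replicate 2. The heart muscle width ranged from 0.805 kb to 1.61 kb, and its call was lost without replicate 2. The ribosomal protein width ranged from 2.66 kb to 2.85 kb and passed either way. The cause was not tested.

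In the list of both replicates together the promoter share was 56.9%, genes marked 67.7% and distal peaks 19.8%. There the heart muscle and mesothelium shares turned (75% each), as did the forebrain width (2.39 kb) and the widest-domain shares of cartilage (0%) and forebrain (7.14%), while alveolar products (1.46 kb) and ribosomal proteins (3.06 kb) passed. With peaks found in both replicate lists the Hox share lost its call (82.1%), the mesothelium and autonomic shares turned by a shift of the background (66.7% each), and ribosomal proteins passed (2.77 kb).

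With the gene's own 5′ end the promoter share was 54.8% and genes marked 63.1%. The Hox share lost its call (76.9%), the heart muscle share passed as lower (25%), Hox widths passed as narrower (1.65 kb), ribosomal proteins passed (2.77 kb), and the forebrain width turned (2.39 kb). With windows of 2.5 kb the promoter share was 71.7%, genes marked 67.7%, the autonomic share turned (73.3%), and Hox (1.83 kb) and ribosomal protein widths (2.77 kb) passed. With windows of 500 bp skeletal muscle lost its width call (1.66 kb), and the mesothelium width (2.31 kb) and autonomic share (66.7%) turned. The cause was not tested.

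Joining over 3 kb, which widens domains by construction, turned the widths of alveolar products (2.38 kb), blood and immune (3.97 kb), forebrain (2.39 kb), heart muscle (2.48 kb) and mesothelium (2.43 kb) and ended the skeletal muscle call (2.09 kb). Among the widest domains it lowered the epithelial share to 48.1%, still past the threshold, brought blood and immune past it (33.3%) and turned forebrain (7.14%). Without joining the forebrain width passed as narrower (1.61 kb), mesothelium turned (2.26 kb) and ribosomal proteins passed (2.77 kb). The widest 10% turned skeletal muscle (14.3%).

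With 1 gene per domain the Hox width passed as narrower (1.69 kb), mesothelium turned (2.26 kb) and ribosomal proteins passed (2.77 kb). Among CpG-rich promoters 4 lists were called by width, cell cycle lost its call (3.41 kb), Hox passed as narrower (1.65 kb), and the widest-domain shares of alveolar products, blood and immune, and cartilage turned (0% each). Among CpG-poor promoters 4 lists were called by width, heart muscle (1.02 kb) and skeletal muscle (1.03 kb) lost their calls though narrower than with all promoters, Hox (2.21 kb) and blood and immune (2.09 kb) widths turned, and for marked shares epithelial regulators (88.9%) and alveolar products (32.0%) lost their calls while cartilage passed (90%). Both alternatives test fewer genes. Whether that is the cause was not tested.

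Distal peaks were 28.5% over 1 kb, 11.5% over 10 kb and 23.9% with protein-coding starts only, by construction. An overlap of at least 50% gave a promoter share of 49.9%, 78.3% of replicate 2 peaks shared and a rank concordance of 0.928, and ranks by peak width gave 0.962.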

Other observations

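The test of gene families in this part was chosen after the widest domains were seen, and the values on other gene types and chromosomes belonged to no planned test. Some non-coding genes lay in domains at lung regulators, and the examples were chosen after their values were seen, with no count or test. Fendrr, the long RNA transcribed away from Foxf1, lay in the 12.9 kb domain of that gene, Sfta3-ps in the 20.7 kb domain of Nkx2-1, and Crnde in the 15.1 kb domain of Irx5. Hoxb5os and the microRNA gene Mir10a lay in the 31.0 kb domain of Hoxb3 to Hoxb6. Of 5854 lincRNA genes 15.4% were marked, with replicates at 16.0% ± 1.01 (SD, n = 2), and of 2959 antisense genes 35.7%, with replicates at 36.2% ± 0.789 (SD, n = 2). Of 190 bidirectional promoter RNA genes 93.7% were marked and of 9940 processed pseudogenes 1.93%. Among genes with no start of their own within 1 kb of a protein-coding start, 565 of 5461 lincRNA genes (10.3%) and 247 of 1871 antisense genes (13.2%) were marked. Their domains could still hold a protein-coding start, as did those of the lincRNA gene Gm44948 (Nr2f2) and of Hoxb5os. These shares therefore do not count marking apart from protein-coding genes.

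The marked share of protein-coding genes varied between chromosomes. It was highest on chromosome 12 at 80.2%, and lower on chromosomes 7 (54.8%) and 14 (56.0%) and on X (490 of 948, 51.7%). On Y 4 of 183 genes were marked, Ddx3y, Eif2s3y, Kdm5d and Uty, in tissue pooled from both sexes. These values were not tested.

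A hypothesis was that families of developmental regulators are over-represented among the widest 5% of domains. Of 21 families set by symbol, 7 had a higher share at an adjusted p of 0.05 or less by Fisher's exact test, the highest of the 7 being 0.0350. They were Fox (9 of 39 marked genes), Sox (7 of 18), Tbx (5 of 11), Gata (3 of 5), Irx (4 of 6), Meis (2 of 3) and, by symbol, Bmp (3 of 10). The Gata members were led by Gata6 at 11.9 kb, Gata3 at 8.59 kb and Gata5 at 5.30 kb. The Klf (3 of 16; adjusted p 0.114), Wnt (3 of 18; 0.118), Fgf (3 of 19; 0.118) and Nkx (1 of 11; 0.650) families were not called. Nor were 5 regulator families with no gene that wide, Pax (0 of 8), Lhx (0 of 7), Dlx (0 of 6), Zic (0 of 5) and the sine oculis homeobox genes (0 of 6), with adjusted p 1 each, so the hypothesis held for 6 of 13 regulator families and not for regulator families at large. Of the 5 families of other functions 0 were called by Fisher's exact test, with 1 at an unadjusted p under 0.05, Rab, which had no gene that wide (0 of 67). The Bmp call at 0.0350 counts Bmp1, which encodes a procollagen metalloproteinase rather than a Bmp ligand and whose domain was the one it shares with Sftpc. The family test shares genes with the lung lists, so it is no independent evidence.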
